A study of Mus musculus with 33 samples.

How the data were processed

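The series held 18 aCGH arrays of mouse prostate tumour DNA against tail DNA (5 G3 and 13 G4 tumours) and 15 Affymetrix arrays of tumour RNA (5 G3 and 10 G4). The groups and tumour numbers came from the labels. By the labels, tumour DNA was labelled with Cy3 (green) and tail DNA with Cy5 (red) on every array, with no dye swap.

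The deposited scanner files held spot intensity values for both channels, made per the file headers with Agilent Feature Extraction 9.5.3.1 (7 arrays) or 10.5.1.1 (11 arrays). Per the file headers, the processed intensity had its background treated by the software, with spatial and multiplicative detrending, and was dye-normalized by the linear method. The deposited LogRatio values are log10 of red over green, per the file headers, and the deposited series table of the aCGH arrays held the same log10 values with the sign turned in all matched spots (100%). Its column medians, from -0.0128 to 0.00475, show no further centring. The series table served only for this check. The deposited expression table held one intensity per probe set, MAS5 signals on a linear scale per the labels, with the MAS5 version not given in the sources used here. Its trimmed mean signal differed between arrays (107 to 211), so the values were not scaled to a common target. All per-sample columns of the series tables matched a sample (0 columns not used).

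The arrays were of an older design (14 arrays, 235402 probes) and a newer one (4 arrays, 411078 probes, all of G4 tumours). Positions on the older design were those of mm7 where the headers stated a build (7 arrays) and identical on the 7 arrays whose headers stated none. The newer design used mm9. The designs shared 214962 probe names (91.3% of the smaller design). The mm9 positions printed in the files of the newer design were used for the shared probes on all arrays, by probe name, and no coordinates were converted. Among shared probes, 1439 lay on different chromosomes in the files of both designs and were kept at their mm9 position. The analysis used 214434 probes, 202636 autosomal and 11798 on the X chromosome, with a median spacing of 8145 bp. Gene names were those of the files, for 144283 of the used probes. Of 25811 gene names, 15697 matched the reference table of mouse genes by accession, 297 by symbol and 222 by synonym, and the other 9646 kept the file's name.

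Log2 of processed green over processed red was averaged over spots of a probe, leaving out control spots and spots with outlier flags (0.0558% to 0.823% of spots per array). Saturated spots were kept. Each array was centred on its median over autosomal probes, with no loess. Arrays correlated with each other from -0.25 (8591 and 8781) to 0.79 (X11923 and 11959) over autosomal probes. Profiles were segmented per chromosome by exact penalised least squares, with at least 5 probes per segment and a penalty of 5 times the noise variance times the natural log of the number of probes. Segments at or beyond ±0.2 were called gained or lost. Bins of 1 Mb with at least 10 probes gave 2389 autosomal bins. A bin was recurrent when more tumours had it gained (or lost) than the 95th percentile of the genome-wide maximum over 1000 random rotations of each tumour's profile along the autosomes. Adjacent recurrent bins were joined to 16 gained and 21 lost regions, of which the highest peak per chromosome is printed.

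The targeted genes were tested by exact two-sided sign tests of the mean over the gene's probes minus the median of probes within 1 Mb. Altered share, breakpoints and chromosome means were compared between G4 and G3 by exact two-sided permutation tests over all 8568 splits of 18 tumours into 13 and 5. Scan dates gave 4 batches: A with 3 G3 and 4 G4 arrays, B with 1 G4 array, C with 2 G3 and 4 G4 arrays and D with the 4 arrays of the newer design, all G4. Values within batches A and C and with batch as a block are given beside the pooled ones. For the expression arrays, batches were not given in the sources used here. Bins and expression were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. Expression was log2 of signal plus a pseudocount of 16, so fold changes of low probe sets are understated. The 64 control probe sets were left out, and probe sets below the 40th percentile of mean log2 signal were filtered, leaving 27022. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and correlations over tumours used 100000 permutations.

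The design fixed one probe set per gene, tests of 22 gene lists, the correlation of copy number with expression of the same gene, and of gene list scores with altered share. A table pairing probe sets with genes was not used here, so these tests were not run and expression was tested per probe set. The rule for named genes, set before the data were examined, named Pten and Trp53 in every tumour, each of 80 cancer copy number genes gained or lost in at least 5 of 18 tumours, and the peak bins and listed genes of recurrent regions. Probe sets were limited to 2 in each direction. The rule for focal events, the single deleted probes and the correlation of all probe sets with all bins were added after the data were seen.

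Segmentation was tested on simulated profiles with the real probe map and noise of each array's size, drawn independently per probe. There were 684 breakpoints per step size on 18 arrays of 202636 autosomal probes. Of these, 87.6% were recovered within 5 probes at a step of 0.2 and 100% at 0.4. False breakpoints numbered 43 at 0.2 and 0 at 0.4. The simulated noise held no wave along the genome, so false breakpoints from such a wave were not tested. The recurrence test, on 2389 simulated bins, called 0 bins without a shared region and 50 of 50 shared bins. The simulated events lay at random places, as in the rotations, and the shared region was given to more tumours than the thresholds of the real data. Fewer rotations were used than for the real data, and no wave was simulated. The simulation therefore does not show how the test behaves near its threshold or with a wave. For the expression comparison, limma on 27022 simulated probe sets with 200 changed recovered 36% at a log2 change of 1 and 95.5% at 2. For the bin comparison, limma on 2389 simulated bins with 200 changed recovered 17.5% at a difference of 0.2 and 84.5% at 0.4. Both limma simulations drew noise independently per probe set or bin, so neighbouring bins that move together were not simulated. The correlation counts, on 5000 simulated probe sets of which 300 followed a bin, gave an excess of 1140 against at most 230 in random pairings. The other simulated probe sets varied independently of each other. Random pairings of the real data gave excesses of up to 6750, so the simulation does not show that an excess of 1140 could be detected there.

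Alternatives covered normexp background correction (offset 50), centring on the mode, the segmentation penalty doubled or halved, all probes of each design, only the older design, call thresholds of 0.1 and 0.3, bins of 2 Mb, a flank of 5 Mb, permutation or block by scan batch, pseudocounts of 1 and 64, no filter or the 60th percentile, quantile normalization, trend and robust eBayes, array weights, and leaving out each tumour in turn. Normexp used median spot signals, because mean signals of the green channel were not in all files used here. Correction for GC content was not run, because probe sequences were not used here. Added after the data were seen were removal of the linear trend of log2 ratio on local probe density, breakpoints with a step of at least 0.2 between segments of at least 1 Mb, and leaving out 3 doubted arrays. Local density was counted in a window of 1 Mb centred on the probe.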

Results

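Prostate tumours from mice carrying LSL-mTert, an inducible telomerase allele, with prostate-directed deletion of Pten and Trp53 (PB-Pten/p53 in the labels) were profiled on DNA and RNA arrays. The labels place each tumour in the G3 or the G4 generation and describe a model of reactivated telomerase after telomeres had become dysfunctional. Copy number was measured by array comparative genomic hybridisation (aCGH) in 18 tumours, 5 from G3 and 13 from G4, each against tail DNA. Expression was measured under 15 of the same tumour numbers, 5 from G3 and 10 from G4. The suffixes after the number differ between DNA and RNA labels (for example A4 and PT for 7106), and 11819 carries PM where the other RNA labels carry PT. The labels do not explain these suffixes, so DNA and RNA were matched by number alone. Tumours are named here by their generation and the tumour number in their labels, with the X of the label where only DNA was profiled under that number. The labels do not state that each tumour came from a separate animal, so p-values measure the spread between these tumours.

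Copy number is given as log2 of tumour over tail, where tumour is the green (Cy3) and tail the red (Cy5) channel by the labels. The probe noise (the SD of 1 probe, estimated from differences between neighbouring probes) ranged from 0.08 to 0.25 over the 18 arrays. The median green signal over background ranged from 5.23 to 25.8 and the median red from 2.50 to 19.1. The number of arrays, not of probes, limits the precision of each comparison between generations. Positions are in mm9.

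The targeted genes were examined first, because the model deletes them in prostate epithelium. Over the 18 tumours, the mean of the 15 Pten probes (chromosome 19, 32832966 to 32898406) minus the median of the 167 probes within 1 Mb was -0.03 ± 0.08 (SD, n = 18). It was below 0 in 11 tumours (exact two-sided sign test, p = 0.481). One Pten probe stood apart, and it was singled out after its values were seen. At position 32874413 to 32874472, log2(tumour/tail) minus the flank was -1.02 ± 0.45 (SD, n = 18) and below 0 in 18 of 18 tumours. The other 14 Pten probes averaged 0.04 ± 0.08 (SD, n = 18) relative to the flank. These 14 probes therefore did not report on the deletion.

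The mean of the 3 Trp53 probes (chromosome 11, 69393563 to 69404744) relative to its flank was -0.38 ± 0.23 (SD, n = 18), below 0 in 16 tumours (exact two-sided sign test, p = 0.00131). The middle probe, at 69397121 to 69397180, carried this loss with -1.34 ± 0.53 (SD, n = 18) and was below 0 in 18 of 18 tumours. It too was singled out after its values were seen. The remaining 2 Trp53 probes averaged 0.09 ± 0.17. Among 198579 autosomal probes with values on every array, ranked by their mean distance from their own segment, the Trp53 probe was rank 1 and the Pten probe rank 2 from the bottom. Their mean distances were -1.30 and -1.03, and the probe at rank 3 (chromosome 5, 113756902) had -0.94. Lying below the own segment in all 18 tumours was shared by 566 of these probes.

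At the deleted Pten probe, the G3 tumours 7523, 7526, 8584, 11563 and 11756 had -0.74, -0.60, -1.27, -1.05 and -1.10 relative to the flank. At the deleted Trp53 probe the same tumours had -1.25, -0.61, -1.45, -1.26 and -1.52. The G4 tumours 7106, 8589, 8591, 8781, 9492, 9493 and X10025 had -0.86, -1.29, -0.58, -0.71, -0.73, -0.83 and -1.12 at the Pten probe and -1.28, -1.33, -0.42, -0.85, -1.30, -1.71 and -1.18 at the Trp53 probe. The G4 tumours 10118, 11649, 11819, X11923, 11959 and X11960 had -2.22, -0.19, -1.40, -0.99, -1.55 and -1.21 at the Pten probe and -2.63, -0.69, -1.98, -1.36, -1.95 and -1.29 at the Trp53 probe. The depth at both probes did not differ between generations beyond the spread: G4 minus G3 was -0.10 for Pten (exact permutation test, p = 0.688) and -0.16 for Trp53 (p = 0.574). Within scan batch A the differences were 0.01 and 0.13, and within batch C 0.09 and 0.07.

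**Figure D1:**
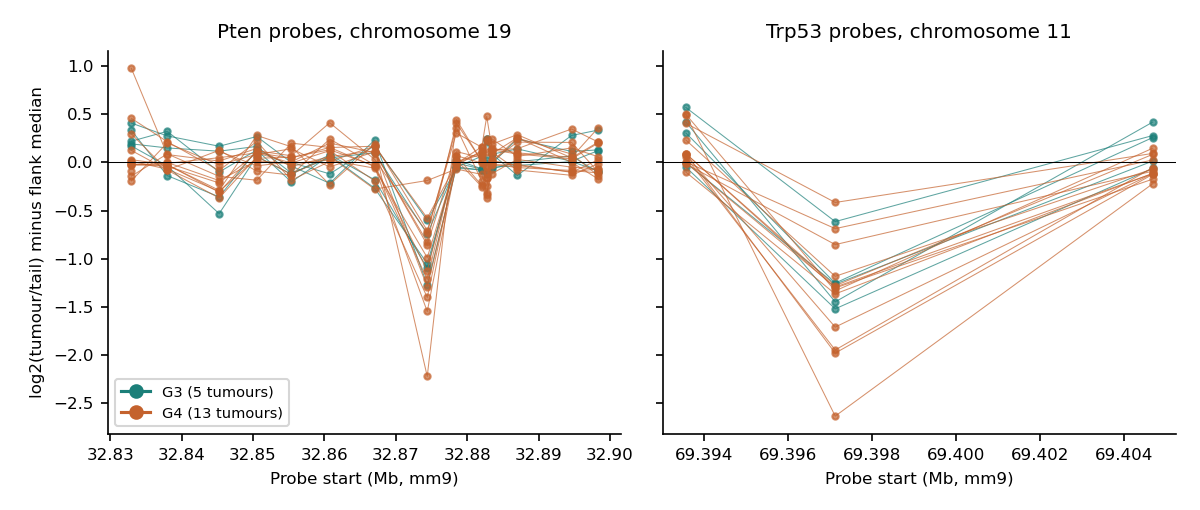
log2(tumour/tail) minus the median of the flanking probes (vertical axis) at each probe of Pten and Trp53 by its mm9 start in Mb (horizontal axis), with 1 line per tumour. A single probe in each gene lies below 0 in all 18 tumours, with means of -1.02 for Pten and -1.34 for Trp53.

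The next comparison asked whether the amount of genome alteration differed between generations, since later generations inherit shorter telomeres. The altered share is the percent of autosomal probes in segments at or beyond ±0.2. It was 28.0% ± 12.5 in G4 (SD, n = 13) and 36.2% ± 11.7 in G3 (SD, n = 5), a difference of -8.14 percentage points (exact two-sided permutation test over 8568 splits, p = 0.223). The gained share was 15% ± 7.10 in G4 and 20.3% ± 6.28 in G3 (p = 0.163 by the same exact test), and the lost share 13% ± 6.74 and 15.9% ± 6.23 (p = 0.424). Arrays were scanned in 4 batches, of which A (3 G3 and 4 G4) and C (2 G3 and 4 G4) held both generations. The difference in altered share was -5.20 within batch A (exact p = 0.457) and -18.7 within batch C (exact p = 0.267). With batch as a block it was -11.1 (exact permutation within batches over 525 splits, p = 0.166).

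The number of autosomal breakpoints per tumour was 194.6 ± 156 in G4 (SD, n = 13) and 282 ± 186 in G3 (SD, n = 5), a difference of -87.4 (exact permutation test, p = 0.335). Within batch A the difference was -49.9 (exact p = 0.771), within batch C -43.5 (exact p = 0.4) and with batch as a block -47.1 (p = 0.575). Breakpoints ranged from 36 to 558 per tumour. The 4 highest counts (tumours 7523, 8589, 8591 and 7526) were on arrays of batch A. On these 4 the mean log2 ratio of 1 Mb bins correlated with the log2 number of probes per bin, within chromosomes, with r from 0.486 to 0.556.

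**Figure D2:**
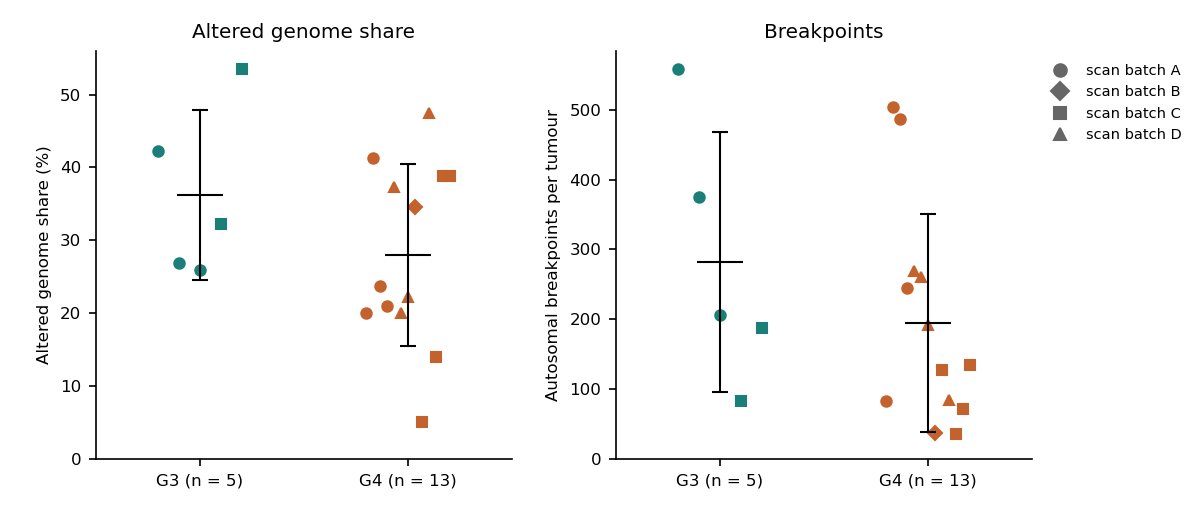
Altered genome share in percent (left) and autosomal breakpoints (right) per tumour, by generation, with symbols for scan batch and with mean and SD as bars. The generations overlap in both measures: the altered share spans 5.08% to 47.5% in G4 and 25.9% to 53.6% in G3.

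Recurrent alterations were sought as 1 Mb bins gained or lost in more tumours than 1000 random rotations of the profiles allow. Of 2389 bins, 188 were recurrently gained (in more than 10 tumours) and 116 recurrently lost (in more than 9 tumours). The gained bins lay on chromosomes 3, 5 and 15, and the lost bins on chromosomes 7 and 8. Chromosome 15 was gained along its whole length: all 101 of its bins were recurrent, each gained in at least 15 tumours, and the bin at 27000001 to 28000000 was gained in 18 of 18 (5 G3 and 13 G4, mean 0.57 ± 0.26 SD). On chromosome 3, 68 of 157 bins were recurrently gained, with a peak at 101000001 to 102000000 in 12 tumours (5 G3 and 7 G4, mean 0.31 ± 0.18). On chromosome 5, 19 of 147 bins were recurrently gained, with a peak at 125000001 to 126000000 in 12 tumours (4 G3 and 8 G4, mean 0.31 ± 0.22). Chromosome 8 had 79 of 126 bins recurrently lost, with a peak at 131000001 to 132000000 in 13 tumours (4 G3 and 9 G4, mean -0.29 ± 0.17). Chromosome 7 had 37 of 138 bins recurrently lost, with a peak at 15000001 to 16000000 in 12 tumours (3 G3 and 9 G4, mean -0.29 ± 0.12).

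Averaged over whole chromosomes and 18 tumours, chromosome 15 had a mean of 0.48 ± 0.24 (SD, n = 18) and was above 0 in 18 tumours. Chromosome 5 had 0.25 ± 0.20 and chromosome 3 had 0.23 ± 0.16, each above 0 in 17 tumours. Chromosome 17 had 0.14 ± 0.11 and was above 0 in 16. Chromosome 8 had -0.20 ± 0.18 and was below 0 in 16 tumours, and chromosome 7 had -0.16 ± 0.12 and was below 0 in 17.

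**Figure D3:**
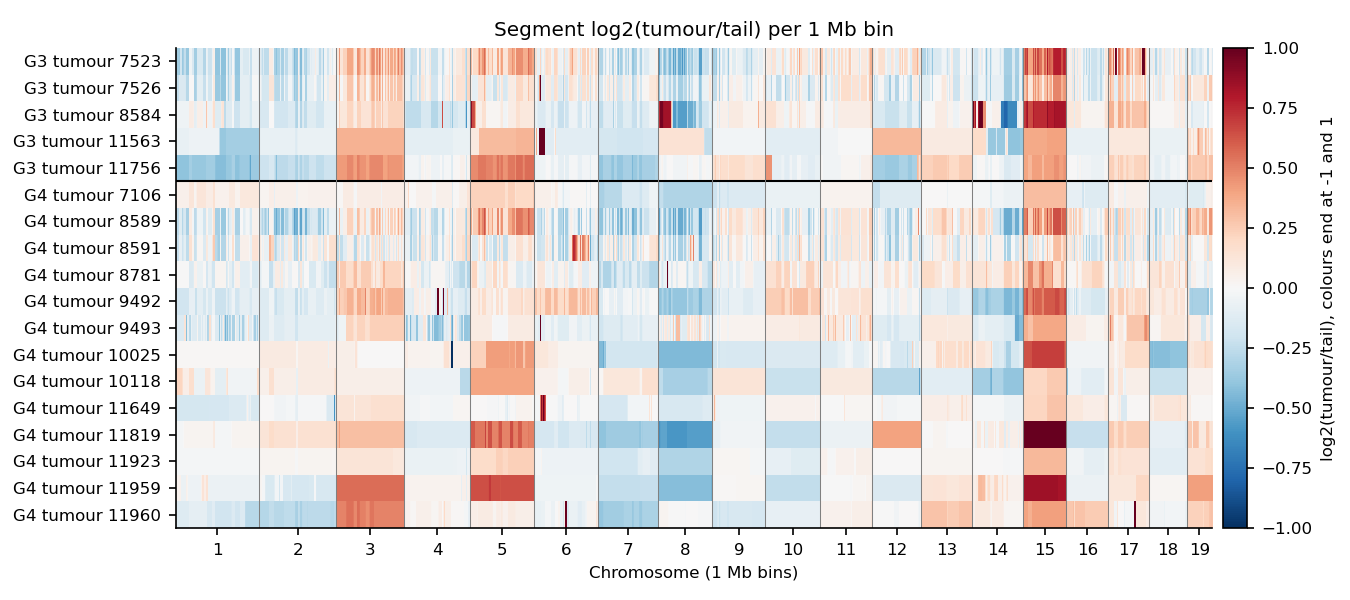
Segment log2(tumour/tail) in 1 Mb bins along the 19 autosomes (horizontal axis) for each tumour (rows, G3 above the line and G4 below), with red for gain, blue for loss and colours that end at -1 and 1. Chromosome 15 had a mean of at least 0.2 in 17 of 18 tumours.

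**Figure D4:**
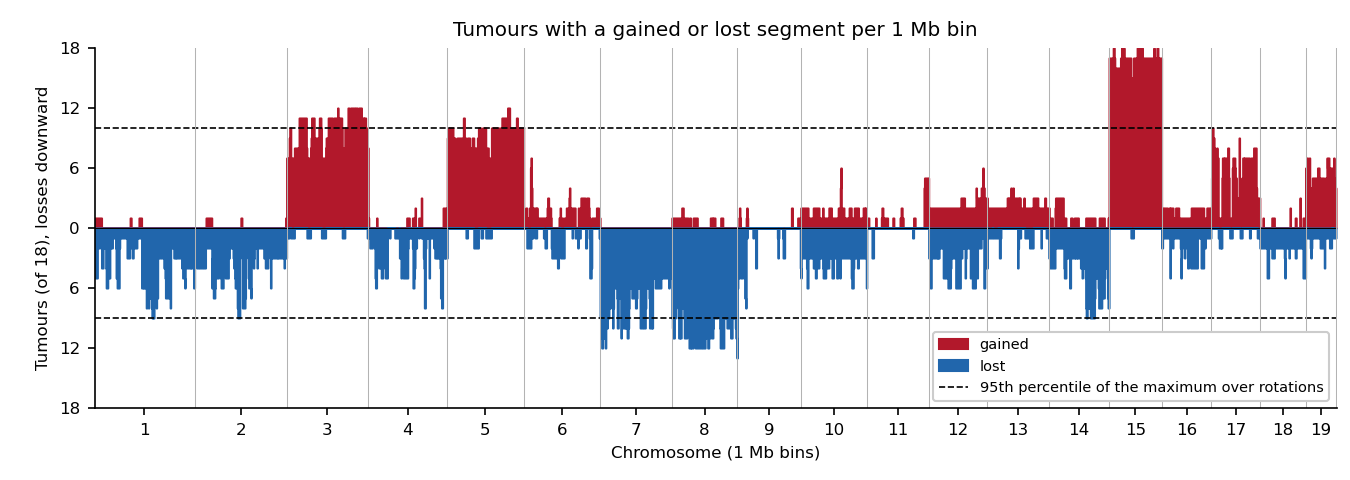
Number of tumours of 18 (vertical axis, losses downward) with a segment gained or lost by at least 0.2 in each 1 Mb bin along the autosomes (horizontal axis). The dashed lines mark the 95th percentile of the genome-wide maximum over rotations, 10 tumours for gains and 9 for losses, exceeded by 188 and 116 bins.

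Of 80 mouse genes on a list of cancer copy number genes fixed before the data were examined, 24 were gained or lost in at least 5 of 18 tumours. Listed genes without a named probe, such as Braf, Ccnd1 and Cdkn2b, could not be called. Inside the recurrent regions lay Myc on chromosome 15, Pik3ca, Fbxw7, Mcl1 and Nras on chromosome 3, and Wwox on chromosome 8. Myc, with 1 probe, was gained in 17 tumours (5 G3 and 12 G4) with a mean of 0.46 ± 0.26. Pik3ca, Fbxw7, Mcl1 and Nras were each gained in 11 tumours, with means from 0.26 to 0.28. Wwox was lost in 10 tumours with a mean of -0.24 ± 0.15, and Cdh1 and Zfhx3, on the same chromosome, in 9 each. Brca2 was gained in 10 tumours and Cdk6 in 9, both on chromosome 5. On chromosome 17, Cdkn1a and Tsc2 were gained in 7 tumours each and Chd1 in 6. On chromosome 7, Akt2 and Ccne1 were lost in 6 tumours each and Fgfr2 in 5. Akt3 on chromosome 1 and Etv1 on chromosome 12 were lost in 5 tumours each, with Etv1 gained in 2. Akt1 was gained in 6 tumours and lost in 1, Jak2 was gained in 5 and lost in 1, and Stk11 was gained in 6 and lost in 3. The segments over Pten as a whole were gained in 5 tumours and lost in 2. Fgfr1 was lost in 7 tumours and gained in 2. Met was gained in 7 tumours (3 G3 and 4 G4) and lost in 0.

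Focal high-level events were listed by a rule set after the profiles were seen: neighbouring segments at or beyond ±1, joined over gaps of up to 1 Mb and holding at least 20 probes. Spans run from the first to the last joined segment and include the gaps, while means and probe counts cover only the segments at or beyond ±1. The rule gave 28 amplified events in 11 tumours and 2 deleted events. The only event in G4 tumour 11819 was a gain of 99.4 Mb of chromosome 15, which is not focal. The only event in G4 tumour 8589 was on chromosome 12 (114842320 to 116301825), in 5 short segments with 25 probes. Short steep segments of this kind are taken up below, with inherited differences between tumour and tail DNA as a candidate explanation. Met on chromosome 6 lay inside an amplified event in 5 tumours, 2 from G3 and 3 from G4. The interval common to these 5 events ran from 17410947 to 17538713 (128 kb, 18 probes). Its named genes were Met and 3 cDNA accessions, which are not printed. The segment values at Met in the 5 tumours ranged from 1.18 in G3 tumour 7526 to 4.34 in G4 tumour 9493. The amplified event around Met in G3 tumour 11563 spanned 12.7 Mb in 22 segments, with a mean of 2.84. Tumour X11960 had an event of 0.791 Mb around Met with a mean of 1.19, and tumour 11649 an event of 2.07 Mb with a mean of 1.51. In G4 tumour 8781, an amplified event with Fgfr1 spanned 2.56 Mb of chromosome 8 (24206646 to 26770011), with a mean of 2.67. In G4 tumour 9492, amplified events spanned 4.54 Mb (78065939 to 82604647) and 2.01 Mb (92812441 to 94819127) of chromosome 4, with means of 2.61 and 2.54. In G3 tumour 7523, an amplified event of 13 segments spanned 5.53 Mb of chromosome 17 (80630752 to 86158989), not all of it amplified, with a mean of 2.26. The deeper of the 2 deleted events, on chromosome 4 from 111656718 to 113994689 in G4 tumour X10025, had a mean of -3.26. Its span also held segments at -0.16 and 0.21, which the mean leaves out. The mean of -3.26 is deeper than the deleted Pten and Trp53 probes of that tumour (-1.12 and -1.18), and the labels do not state whether the tail DNA came from the same animal. Of the listed cancer genes with a named probe, only Met, Fgfr1 and, within a gain of nearly all of chromosome 15 in G4 tumour 11819, Myc lay inside an event.

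**Figure D5:**
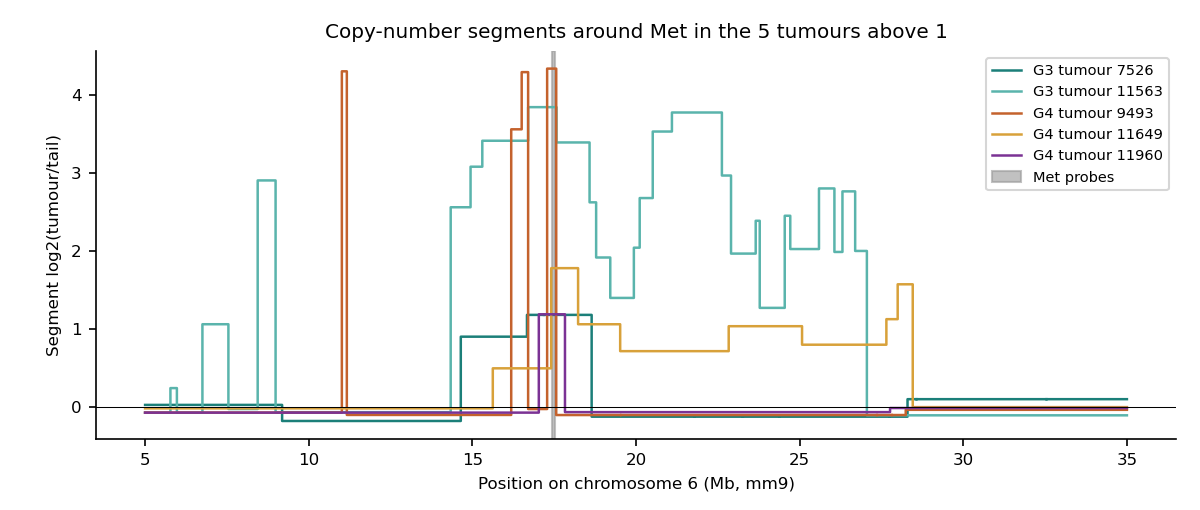
Segment log2(tumour/tail) (vertical axis) along chromosome 6 from 5 to 35 Mb in mm9 (horizontal axis) for the 5 tumours with Met above 1, with the Met probes shaded. All 5 lines are at or above 1.18 over the shaded part and differ in extent on either side.

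Copy number was then compared between generations by chromosome and by bin, to ask whether regions differed. Of 19 autosomes, 0 passed an adjusted p of 0.05 (exact two-sided permutation test with Benjamini-Hochberg adjustment). The lowest adjusted value, 0.146, belonged to chromosomes 1 and 17. Chromosome 1 had a mean of -0.05 ± 0.08 in G4 and -0.19 ± 0.12 in G3, a difference of 0.14 (exact p = 0.0111). The chromosome 1 difference was 0.10 within batch A and 0.19 within batch C, and 0.14 with batch as a block (adjusted p = 0.163). Chromosome 17 had 0.11 ± 0.08 in G4 and 0.24 ± 0.13 in G3, a difference of -0.13 (exact p = 0.0154). The chromosome 17 difference was -0.25 within batch A and -0.07 within batch C, and -0.17 with batch as a block (adjusted p = 0.109). Of the 2389 bins, 0 passed an adjusted p of 0.05 in limma, where the smallest adjusted p was 0.189, and 212 had an unadjusted p under 0.05. The lowest p was at chromosome 1, in the bin starting at 142000001, with -0.09 in G4 and -0.41 in G3. With batch as a block in limma, 0 bins passed (smallest adjusted p = 0.349).

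Expression was compared between 10 G4 and 5 G3 tumours on 27022 of 45101 probe sets, those above the 40th percentile of mean log2 signal and not controls. The files pair no gene names with the probe sets, so probe sets are given by identifier. The median log2 fold change (G4 minus G3, on the scale of log2 of signal plus 16) over all tested probe sets was 0.22, and the trimmed mean signal of the deposited arrays ranged from 107 to 211. Relative to this shift, a fold change of 0.22 stands for no difference. In limma, 1 probe set passed an adjusted p of 0.05. It was 1437873_at, with 6.33 ± 0.17 in G4 (SD, n = 10) and 5.10 ± 0.36 in G3 (SD, n = 5), a log2 fold change of 1.24 and an adjusted p of 0.0279 in limma, and it was above the G3 mean in 10 of 10 G4 tumours. After quantile normalization between arrays its log2 fold change was 1.05 with an adjusted p of 0.0845 in limma and 0 probe sets passed. With the deposited scaling, 3324 probe sets (12.3%) had an unadjusted p under 0.05, and with quantile normalization 1992. The lowest probe sets by t statistic, given as values only, were 1457769_at with a log2 fold change of -3.11 and 1440145_at with -2.54 (adjusted p = 0.246 in limma for both).

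The series states that expression was set against copy number. Without gene names for the probe sets, a relation of a gene's copy number to its own expression was not analysed here. In its place, and chosen after the data were seen, each of 27022 probe sets was correlated with each of 2389 bins over the 15 tumour numbers with both measurements. The count of correlations at or above 0.85 was set against the count at or below -0.85. There were 4287 at or above and 3245 at or below, an excess of 1042, and 99 random pairings of the tumours gave excesses of up to 6750 (p = 0.2 by permutation of the pairing). The p-values of these counts are one-sided, for an excess at least as high. Chromosomes pulled in opposite directions: counts at or above and at or below were 1071 and 39 on chromosome 5 and 914 and 191 on chromosome 1. They were 100 and 1216 on chromosome 8 and 267 and 795 on chromosome 10. With quantile normalization of the expression values the excess was 2982, above the highest of the 99 random pairings, 1897 (permutation p = 0.010, the smallest that 99 pairings can give). The call therefore depended on the scaling of the expression arrays.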

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

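The comparison with other splits of the tumours and the check without tumour 8591 were chosen or read after the result was seen. Of 44 sets of values within a group of tumours, 3 held a value far from the others, and chance gives about 1 in 20 sets. The sets came from the G3 DNA, G3 RNA and G4 RNA arrays. The G4 DNA arrays were not screened, because the rule covered only smaller groups. The ratio of the 3' to the 5' actin control probe set, a measure of RNA integrity, was 2.00 in G3 tumour 11756 and from 1.16 to 1.21 in the other 4 G3 tumours. In G4 tumour 8591, probe set 1457769_at had a log2 signal of 7.57, against 4.27 to 5.35 in the other 9 G4 tumours. In the same tumour, probe set 1440145_at had 6.92, against 4.15 to 5.07 in the others. Both probe sets were chosen as the lowest in G4 by t statistic, so the flags in 8591 show a G4 tumour on the side of the G3 mean (8.20 and 7.24). Without this tumour, 2 probe sets were lower in G4 at an adjusted p of 0.05 in limma, against 0 with it. No explanation of these 3 values was tested.

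For the 1 probe set past the threshold in the expression comparison, 100 splits of the 15 tumours, the real one included, were fitted with limma. As many probe sets passed in 4 of them, a share under the 0.05 level with the deposited scaling. The highest of the other splits also gave 1, so this count cannot tell the single probe set from chance. The splits were not run with other settings, and the call itself was lost with quantile normalization (adjusted p = 0.0845), a pseudocount of 64 or the filter at the 60th percentile, and in 9 of 15 fits without 1 tumour. For copy number, the real split gave 0 bins, so all 100 of 100 splits had to give as many and the count says nothing about chance. Of the 99 other splits, 4 gave any bins, and the highest gave 177. Neighbouring bins on a chromosome can move together, so the count of 177 alone does not show a structure of the samples, and none was tested. That split set tumours 8781, 9493, 11649, 11756 and X11960 against the rest, from batches A, C and D.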

How the results depend on the processing

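Alternatives set before the data were examined and those added afterwards (probe density trend removed, large-step breakpoints, doubted arrays left out, the single lowest probe, and all settings of the correlation counts) gave 361 values, of which 329 kept their direction and side of the threshold or stayed within 1.5 times the count. None reversed. The altered share stayed lower in G4 without passing 0.05 in 13 of 13 alternatives (-11.3 to -0.28, p from 0.132 to 0.971), as did breakpoints in 12 of 12 (-143 to -47.1, p from 0.135 to 0.575). Leaving out each tumour gave -10.7 to -3.80 for the altered share (-3.80 without G3 tumour 11756, p = 0.57) and -137 to -18.4 for breakpoints (-18.4 without G3 tumour 7523, p = 0.845, and -137 without G3 tumour 11563). The Trp53 loss stayed past the threshold in 4 of 4 (p up to 0.0129), leaving aside the single lowest probe. For Pten, the planned mean stayed near 0, and the single probe with the lowest median, chosen for being lowest, gave -1.02.

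Recurrently gained bins numbered 302 at a call threshold of 0.1 and 115 at 0.3, and lost bins 67 with centring on the mode and 63 on the older design alone (fewer tumours). In both lost-bin settings all bins were among the main 116. With the probe density trend removed there were 135 gained and 98 lost bins. Without the 3 arrays with the strongest trend (fewer tumours) there were 132 gained and 94 lost bins. In each of these settings some of the main gained and lost bins were no longer recurrent, and some other bins became recurrent. Leaving out each tumour in turn gave 188 to 260 gained bins and 71 to 116 lost bins, with the 71 or 72 from leaving out 7523, 8589, 11819 or 11959. In these fits the threshold for gains fell from 10 to 9 tumours and that for losses stayed at 9. Gained bins could therefore only stay or rise, and lost bins only stay or fall. Of the autosomes, 1 passed on the older design alone (chromosome 17, adjusted p = 0.0380), and leaving out each tumour gave 0 to 1 (chromosome 1 without G3 tumour 8584, difference 0.17, adjusted p = 0.0319). Without G3 tumour 11756 the chromosome 1 difference fell to 0.088 (exact permutation test, adjusted p = 0.623). Leaving out each tumour gave 0 to 1 bins higher in G4, the 1 without G4 tumour 8589. Apart from the threshold for recurrent bins, the cause of these changes was not tested.

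For expression in limma, 0 probe sets were higher in G4 with a pseudocount of 64, with the filter at the 60th percentile and with quantile normalization, 2 without tumour 11819, and 154 with array weights, which also gave 15 lower. The smallest adjusted p ranged from 0.000393 to 0.339 over these alternatives. Leaving out each tumour gave 0 to 2 higher and 0 to 2 lower. The single call was lost without any of G3 tumours 7523, 7526, 8584 or 11563 or G4 tumours 8589, 9492, 9493, 11649 or 11959. The correlation counts passed the threshold with quantile normalization (excess 2982) and without G4 tumour 7106 (excess 4838, p = 0.040); leaving out each tumour gave 347 to 5555. The cause was not tested.

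No paired analysis was possible because the labels give tumour numbers, each found in only 1 generation, and no replicate numbers. Not run were correction for GC content and all alternatives of the gene list, same-gene and list score tests. The red signal, at 2.50 times background on the dimmest array, limits small differences.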

Other observations

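The tests on rotated breakpoints, on removal of the density trend and on segment depth had their outcomes set before their results were seen, and the tests on opposite signs, on random placements, on depth against chromosome values, the exact test on breakpoints and the stricter counts of deep segments were chosen after.

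The 3 arrays with the strongest relation of log2 ratio to probe density (7526, 8589 and 8591, all in batch A) averaged 455 breakpoints, against 171.6 on the other 15. Of their 1366 breakpoints, 77.8% lay within 10 probes of a breakpoint on another of the 3, against at most 17.3% in 100 random rotations. This suggests a wave along the genome fixed by probe position, since breakpoints that arise in separate tumours need not coincide. Removing the linear trend on probe density left a mean of 378 breakpoints, against 143 ± 108 (SD) on the other 15 (exact p = 0.00613, and 0.00490 before), which argues against that trend as the whole cause, although the bound set beforehand, the highest other array (463, tumour 7523), was not passed. Breakpoint counts on these arrays may therefore overstate the rearrangements, and real rearrangements remained untested as the source of part of them. Their altered share may be overstated too, which was not tested. On 7526, 8589 and 8591 it was 26.9%, 41.3% and 23.7%, with a mean of the absolute chromosome means of 0.103, 0.167 and 0.0377. Tumour 11649, not among the 3, had 5.08% and 0.0707. Without the 3 arrays, the altered share in G4 minus G3 was -11.3 (exact permutation test, p = 0.155).

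Segments of at most 0.5 Mb that stepped by at least 0.7 from their neighbour numbered 195 in 13 tumours, with 73 in G4 tumour X10025. In 21 overlapping pairs, different tumours stepped in opposite directions at one place, and in 11 in the same direction, against at most 5 of either kind in 1000 random placements. A candidate explanation is inherited copy-number differences between the tumour DNA and the tail DNA on the array, while places prone to change in tumours stayed open. Of 94 downward segments, 38.3% stepped deeper than the deeper of the deleted Pten and Trp53 probes of the same tumour, but the selecting step alone made all of those in tumour 11649 pass, and some lay inside amplified regions. Without these, 15 of 70 segments in 3 tumours were deeper, and those deeper by more than 2 times the noise of a segment mean minus 1 probe lay at 4 of 24 places (16.7%, joined within 1 Mb, with 7 of 10 segments in the deleted chromosome 4 event) in tumour X10025 and at 0 of 26 elsewhere, which argues against deletions arising in the tumour cells at those 4 places if X10025, by its genotype label, lost both copies of a targeted gene like 11 tumours with probes below -1 by more than 2 times the probe noise, which its own probes did not reach.

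The mean absolute chromosome value rose with the depth of the deleted Pten probe (Pearson r = 0.57, permutation p = 0.0134, adjusted 0.0403 over 9 relations, Spearman rho = 0.645, p = 0.00475, n = 18). Without the 2 tumours farthest in depth r was 0.685, and without the 2 farthest on both measures together it was 0.406 (permutation p = 0.12). Within batch A r was 0.565 (exact p = 0.192, n = 7) and within batch C 0.872 (exact p = 0.00972, n = 6). The altered share was related to depth with r = 0.501 at the Pten and 0.454 at the Trp53 probe. The chromosome 15 mean had r = 0.331 and 0.393. None of these passed, with a lowest adjusted p of 0.0753 (permutation of Pearson r, n = 18). Without the 2 tumours farthest in depth r was 0.436 and 0.521 for the altered share (permutation p = 0.0937 and 0.0390). For chromosome 15 it was 0.681 and 0.663 (permutation p = 0.00347 and 0.00545). Without the 2 farthest on both measures together it was 0.653 and 0.635 for chromosome 15 (permutation p = 0.00591 and 0.00784). For the altered share it was then 0.436 and 0.415 (permutation p = 0.0937 and 0.111). The p-values without 2 tumours were not adjusted. The depths at the Pten and Trp53 probes were related to each other with r = 0.871 (permutation p = 2e-05, rho = 0.787), 0.777 without the 2 farthest, 0.813 within batch A and 0.939 within batch C. Of the copy-number measures above, only the mean absolute chromosome value was related to probe depth at an adjusted p under 0.05 over all 18 tumours. The chromosome 15 mean was related to probe depth only with 2 tumours left out, and there more strongly than over all 18. Different shares of cells without the deletions may set part of the size of the copy-number changes. Weak changes in tumours such as 8591 and 11649 then need not mean fewer alterations. Tumours with other degrees of alteration were not separated from tumours with different shares of such cells.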
